A study of Homo sapiens with 13 samples.

How the data were processed

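RNA-seq was made from total RNA of U2OS cells, an established human osteosarcoma line, that carried stable, puromycin-selected short hairpin constructs. The labels give 1 control library (shCTRL) and 2 libraries numbered 1 and 2 with a short hairpin against ZMYND11. The numbers are taken here to mean different hairpins, called hairpin 1 and hairpin 2, which the labels do not spell out. The series also lists 10 ChIP-seq samples of ZMYND11, Flag-tagged H3.3, H3K36me3 and RNA polymerase II, which are not analysed here.

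The deposited values are RPKM (reads per kilobase of transcript per M reads), 1 value per RefSeq transcript, per the file headers and the position field beside each value. CASAVA 1.8.2, Bowtie 0.12.7 and the hg18 genome build are named in the submitters' processing notes, without their roles. The read counter, the annotation release and whether strand was used are not given in the sources used here. Each file lists 35630 transcripts, isoforms of a gene stand on separate lines, and isoforms can share reads. Transcripts were named through a RefSeq gene table of the GRCh38 assembly, used for names only; 34075 transcripts (95.6%) received a gene symbol and 1555 did not, and those without held 2.68% of the summed RPKM. All coordinates are those of the files, on hg18.

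RPKM values of intronless olfactory receptor transcripts, multiplied by length, fell on whole multiples of a step that differed between libraries, which gave the reads behind each library. The shCTRL library had 26.1 M reads, hairpin 1 had 21.3 M and hairpin 2 had 27.8 M. Of the transcripts used, 48 of 49, 43 of 43 and 36 of 36 came out whole within a tolerance of 0.02 of a read. For a transcript of 2 kb, 1 RPKM is then 52.2, 42.7 and 55.7 reads, and a floor of 3 reads is 0.0575, 0.0703 and 0.0539 RPKM. Such floors cover counting error alone. No 2 libraries held identical values.

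From the RPKM the transcript with the highest mean over the 3 libraries was taken for each of 21585 gene symbols, and the 9875 genes with a mean RPKM of at least 1 were tested. Values were log2(RPKM + 0.5), so ratios of weakly expressed genes are understated. The comparison of the 2 hairpin libraries with shCTRL used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend on mean expression, two-sided, Benjamini-Hochberg adjusted p under 0.05 and the same direction in both hairpins). The design leaves 1 residual degree of freedom, the difference between the hairpins, and limma added 5.26 prior degrees of freedom; the lone control is assumed to vary as the hairpin libraries do. Nothing in the labels says that the 2 hairpin libraries came from separately derived cultures of the same age or batch as the control. Limma's p-values for genes thus measure the spread between these libraries.

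A rule of size with no test counted genes at least 2-fold from shCTRL in the same direction in both hairpins. Because both ratios share the control library, the agreement of the hairpins was set beside 200 simulations of 3 unchanged libraries with the spread per gene taken from the difference between the hairpins, and the same counts were made with each hairpin library in the place of the control. The 29 gene lists (867 entries, 863 in the files) were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists, and again with a correlation estimated from the residuals, which 1 list with a single tested member does not have. Each list's median log2 ratio was also placed among 10000 random lists of its size matched on mean expression in 20 bins. The result of 1 of the 29 lists, which was not called, and the level of 1 gene are not reported here. The lists, the tests and most alternatives were fixed before the data were examined. So was the rule for named genes, which takes ZMYND11, the 12 highest and 12 lowest genes by the hairpin with the smaller ratio, up to 4 members per list with the smallest limma p, and the 5 genes farthest apart in opposite directions.

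The limma step was tested on simulated data with the spread of these libraries. It recovered 0% of genes changed 2-fold, 6% of those changed 4-fold, 30% at 8-fold and 74% at 32-fold (50 genes each). It also called 5 of 9675 unchanged genes. The simulated spread was drawn from limma's own fitted model and was the same in the control. A library that deviates as a whole was not simulated, so false calls from such a deviation were not measured. In the list step a simulated list of 30 genes shifted by 0.5 was called (camera adjusted p = 0.00444), and 0 of 20 unshifted lists were. The simulated genes varied independently, so this does not measure false calls in lists whose members vary together.

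Alternatives were pseudocounts of 0.1 and 1, no filter and a mean RPKM of at least 5, median-ratio scaling and quantile normalization, the mean over a gene's transcripts, eBayes without the trend or with robust fitting, an adjusted p under 0.1, other fold sizes, each hairpin library as the reference, and each hairpin left out. Figures were drawn with matplotlib 3.10.9 in Python.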

Results

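Gene expression was measured by RNA-seq in U2OS osteosarcoma cells after stable depletion of ZMYND11, a chromatin protein that binds histone H3.3 trimethylated at lysine 36. The RNA-seq part of the series held 3 libraries, 1 of cells with a control hairpin (shCTRL) and 2 of cells depleted of ZMYND11, numbered 1 and 2 in the labels and taken here as different hairpins. Reads behind the libraries came to 26.1 M for shCTRL, 21.3 M for hairpin 1 and 27.8 M for hairpin 2. At 1 RPKM or more, 9922 genes were seen in shCTRL, 9961 in hairpin 1 and 9349 in hairpin 2. The gene with the highest RPKM in each library was TPT1, with 2.18%, 2.96% and 2.09% of the summed gene RPKM.

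ZMYND11 was lower in both hairpin libraries. Its main transcript (NM_212479, chromosome 10, 170424 to 285201 on hg18) stood at 9.19 RPKM in shCTRL, 1.05 in hairpin 1 and 1.72 in hairpin 2, that is 11.4% and 18.7% of the control level. A second transcript, NM_006624, gave 6.88, 0.916 and 1.29 RPKM, and the 2 transcripts can share reads. On the log2 scale the mean ratio was -2.39 (SE 0.47, 2 hairpins), with a limma p of 0.00196 that became 0.572 after adjustment over all genes. The targeted gene thus had the direction its labels give in both libraries, without passing the threshold of the genome-wide test.

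The comparison of the 2 hairpin libraries with shCTRL asks which genes differ in RNA level when the H3.3 lysine 36 reader is depleted. Among the genes highest in both hairpins, MMP3, the matrix protease stromelysin-1 (chromosome 11, 102211738 to 102219552), was at 9.64 RPKM in shCTRL, 194 in hairpin 1 and 229 in hairpin 2, or 20.1-fold and 23.8-fold the control. BIRC3, an inhibitor of apoptosis, was at 0.631, 13.7 and 24.7 RPKM, and BCL2A1, an anti-apoptotic BCL2 relative, at 1.77, 27.1 and 54.1. HAPLN1, which links hyaluronan to proteoglycans, was at 20.4, 1.40 and 0.892 RPKM and had the lowest log2(RPKM + 0.5) ratio in the hairpin with the smaller difference, and the fibrillar collagen gene COL11A1 was at 23.7, 2.70 and 2.94. None of these passed the limma test.

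With limma 0 of 9875 genes were called in either direction, 442 had an unadjusted p under 0.05 (204 higher and 238 lower), and the smallest adjusted p was 0.0796, for MYCT1. MYCT1 (chromosome 6, 153060723 to 153087408) was at 0.0756 RPKM in shCTRL, 25.2 in hairpin 1 and 21.9 in hairpin 2, a mean log2 ratio of 5.38 (SE 0.40). MMP3 had a mean log2 ratio of 4.38 (SE 0.42, limma adjusted p = 0.173). The median SE over genes was 0.446 on the log2 scale. In simulated libraries with this spread the test recovered 6% of genes changed 4-fold and 30% of those changed 8-fold, so changes of those sizes were mostly not detectable with 1 control and 2 hairpin libraries. The count became 1 with a pseudocount of 0.1 (MYCT1) and 2 among genes with a mean RPKM of at least 5 (MYCT1 and MMP3).

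By size alone, 165 genes were at least 2-fold higher and 202 at least 2-fold lower than shCTRL in both hairpins. Besides MYCT1, MMP3, BIRC3 and BCL2A1, the 12 highest were LINC00520, a long noncoding RNA (0.956, 77.9 and 18.2 RPKM in shCTRL, hairpin 1 and hairpin 2), the cytokine gene IL24 (0.805, 37.0 and 16.2), FCMR (0.600, 20.2 and 9.06), the pseudogene AADACP1 (1.49, 14.5 and 24.2), SERPINB2, which encodes plasminogen activator inhibitor 2 (0.0804, 3.42 and 7.39), DOCK4 (3.19, 22.6 and 58.9), the phosphatase gene PTPN22 (0.269, 7.24 and 4.17) and SCG5 (5.71, 54.4 and 34.6). IL24 (chromosome 1, 205137411 to 205144107) and FCMR (205143253 to 205162001) overlap, and since strand use was not stated, reads in the shared part cannot be told apart. The control values of MYCT1 and SERPINB2 rest on few reads, so no linear fold is given for them.

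Besides HAPLN1 and COL11A1, 10 more genes made up the 12 lowest by the same rule. The chemokine gene CXCL14 was at 7.03, 0.428 and 0.164 RPKM, IGFBP5, which binds insulin-like growth factors, at 9.56, 0.948 and 0.242, and the heparan sulfate proteoglycan gene SDC2 at 22.9, 3.19 and 1.81. TMEM45A was at 16.8, 1.98 and 1.77, MOXD1 at 10.4, 1.51 and 0.308, and FXYD6 at 12.02, 1.85 and 1.71. More weakly expressed in the control were CCDC85A (4.69, 0.353 and 0.181), SHOC1 (3.31, 0.183 and 0.101), the myosin light chain gene MYL1 (3.38, 0.272 and 0.167) and the homeobox gene HOXA13 (3.69, 0.336 and 0.329). Across the 12 genes the RPKM lay between 6.48-fold under shCTRL (FXYD6 in hairpin 1) and 42.9-fold under it (CXCL14 in hairpin 2).

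The hairpins did not always point the same way: 19 genes were at least 2-fold from shCTRL in opposite directions. The reticulon gene RTN1 was at 15.3 RPKM in shCTRL, 60.2 in hairpin 1 and 1.96 in hairpin 2. The complement protease gene C1S (1.41, 4.95 and 0.225), INKA2 (6.11, 17.2 and 2.15) and CCN3 (9.24, 22.9 and 3.51) were likewise higher in hairpin 1 and lower in hairpin 2. SNORA27, a small nucleolar RNA whose short length can take in reads of its host gene, went the other way (2.13, 0.372 and 6.28).

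**Figure D1:**
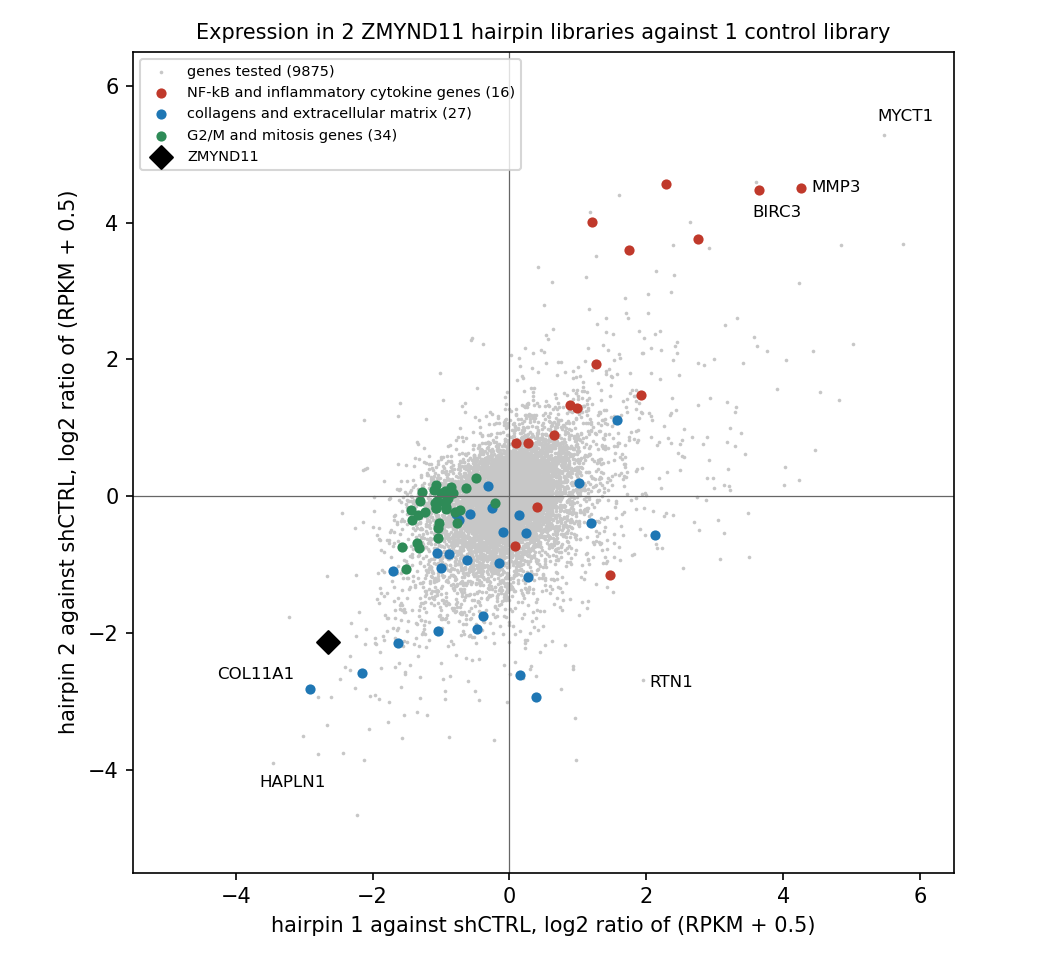
Log2 ratio of (RPKM + 0.5) to the single shCTRL library for 9875 genes, hairpin 1 on the x axis and hairpin 2 on the y axis, with each point a gene and members of 3 gene lists in colour. NF-kB list members lie mostly at upper right (13 of 16 higher in both hairpins), extracellular matrix members mostly at lower left (17 of 27 lower in both), and G2/M members left of 0 for hairpin 1 (34 of 34) and near 0 for hairpin 2.

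How far the 2 hairpins agreed was compared with what a shared control gives by itself. Across genes, which are not independent replicates, their log2 ratios had a Pearson correlation of 0.462 and a Spearman correlation of 0.374. Simulated unchanged libraries with a shared control gave a mean correlation of 0.501 (0.442 to 0.555 over 200 simulations). That mean follows from giving the control the same spread per gene as the hairpins. The covariance was 0.209 against a simulated 0.246, and 62.9% of genes had the same sign against 66.8% (65.5% to 67.8%). Hairpin 1 alone had 487 genes at least 2-fold higher and 579 lower, and hairpin 2 had 351 and 726. Independent lists of those sizes would share 17.3 and 42.6 genes, where 165 and 202 were shared. The simulations with no effect gave 204 (170 to 247) and 203 (168 to 239), so the overlap did not exceed the simulated counts. The 165 higher genes and the same-sign share lay below all 200 simulations. The simulated spread takes in any real difference between the hairpins and is only assumed for the control. The simulations therefore cannot show that the shared control produced the overlap, nor that a shared effect is absent. With 1 control library the control could not be split.

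With each library in turn as the reference, shCTRL had the fewest genes apart at 2-fold and the most at 4-fold. Genes at least 2-fold from the reference in the same direction in both other libraries numbered 367 for shCTRL, 427 for hairpin 1 and 415 for hairpin 2. At 4-fold the counts were 53, 52 and 46. At 8-fold they were 9, 13 and 3. With limma 0 genes were called for each of the 3 references, and 442, 685 and 568 had an unadjusted p under 0.05.

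**Figure D2:**
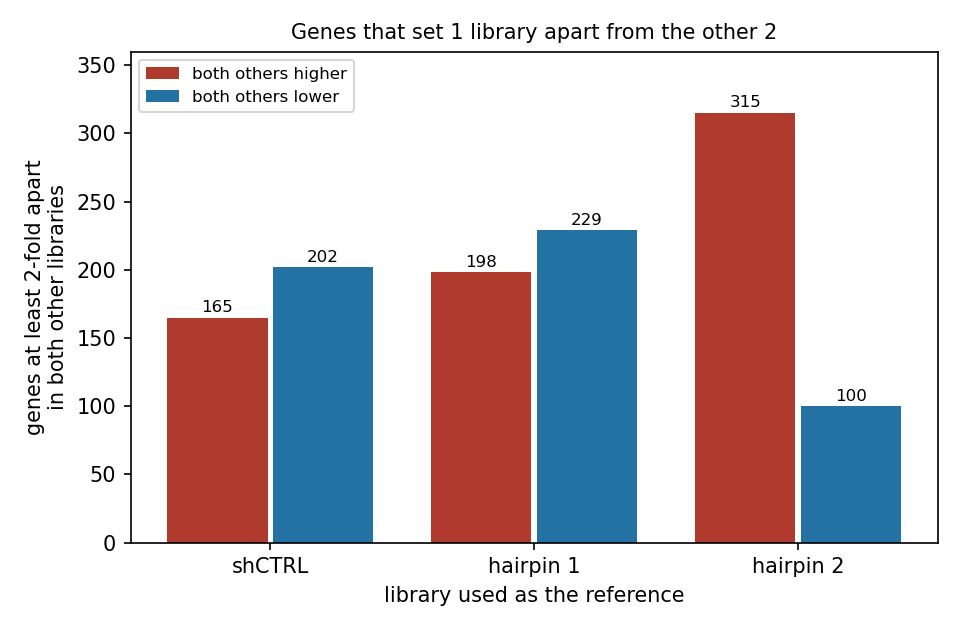
Number of genes (y axis) at least 2-fold higher or lower in both other libraries than in the library named on the x axis, out of 9875 genes. The control as reference gives 165 higher and 202 lower, against 198 and 229 for hairpin 1 and 315 and 100 for hairpin 2.

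Gene lists asked whether groups of related genes stood apart from the other genes when ZMYND11 was depleted. By limma's camera 10 of 29 lists were called at a preset inter-gene correlation. At that preset of 0.01 camera compares members with the other genes and treats them as nearly independent. Its p-values then do not measure the spread between libraries, and are too small where members vary together. With the correlation estimated from 1 residual degree of freedom 0 were, at adjusted p = 0.870 for the MYC target list and adjusted p = 0.793 for the other called lists with more than 1 tested member. That version could hardly call any list with 1 residual degree of freedom. The equal 0.793 is a tie made by the adjustment over lists, and lists that were not called share it. With 1 residual degree of freedom behind it, this adjusted p counts neither for nor against a list. The same test called 9 lists with hairpin 1 as the reference and 10 with hairpin 2, so a call describes how 1 library stands apart from the other 2.

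NF-kB and inflammatory cytokine genes had the highest medians of the lists with at least 3 tested members. Of 29 listed genes 16 passed the filter on the mean RPKM of the 3 libraries, 2 of which are hairpin libraries. Genes weak in shCTRL, such as BIRC3 (0.631 RPKM there), CXCL8 and IL1A, could thus pass through the hairpins. The counts and medians that follow therefore lean towards genes higher in the hairpins, by an amount that was not measured. Of 16 tested members 13 were higher in both hairpins, 0 were lower in both and 8 were at least 2-fold higher in both, with median log2 ratios of 1.24 in hairpin 1 and 1.41 in hairpin 2 (camera adjusted p = 1.55e-14, and adjusted p = 0.793 with an estimated correlation). Both medians were above those of all 10000 matched random lists. The list was also higher in hairpin 2 than in hairpin 1, by a median difference of 0.48 (percentile 99.98). Camera called it with hairpin 2 as the reference too. With limma 0 members were called over all genes, and 6 were adjusted over the list alone: MMP3, BIRC3, SERPINB2, CXCL8, CCL20 and IL1A. The neutrophil chemokine gene CXCL8 was at 0.116, 2.50 and 14.04 RPKM in shCTRL, hairpin 1 and hairpin 2. CCL20, a chemokine gene, was at 0.778, 4.36 and 3.05, and IL1A, which encodes interleukin-1 alpha, at 0.393, 2.50 and 10.4. Markers of blood cells were tested through 1 gene, CD68, a lysosomal protein gene that is also a macrophage marker, at 22.8, 505 and 101 RPKM (camera adjusted p = 0.0124 for this list of 1, for which no correlation can be estimated). The other 15 blood markers reached at most 0.307 RPKM in a hairpin library.

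Immediate-early genes, which respond fast to growth signals, were also higher. Of 22 tested members 13 were higher and 3 lower in both hairpins, with medians of 0.51 and 0.32 (camera adjusted p = 0.000447, and adjusted p = 0.793 with an estimated correlation), and 0 were called over all genes or adjusted over the list alone. MYC was at 11.9, 36.5 and 42.2 RPKM, a mean log2 ratio of 1.68 (SE 0.41). The phosphatase gene DUSP5 was at 1.75, 4.96 and 12.4, MAFF at 1.29, 3.40 and 3.25, and the AP-1 subunit gene FOSL1 at 11.6, 19.4 and 46.6.

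MYC target genes, mostly of ribosome biogenesis, differed between the hairpins. Their median was -0.05 in hairpin 1 and 0.45 in hairpin 2, with 16 of 37 members higher and 3 lower in both (camera adjusted p = 0.00753, and adjusted p = 0.870 with an estimated correlation). The list's direction thus rests on hairpin 2. All 37 members were higher in hairpin 2 than in hairpin 1, and camera called the list with either hairpin as the reference too. TFB2M was at 8.44, 14.03 and 15.9 RPKM, RRP12 at 3.46, 5.81 and 5.98, and NOP56 at 57.1, 84.6 and 98.0. Cytosolic ribosomal protein genes, whose many pseudogenes can share reads, had small ratios in the same direction, with 53 of 75 higher and 2 lower in both, medians of 0.26 and 0.18 and 0 members at least 2-fold higher in both (camera adjusted p = 0.000507, and adjusted p = 0.793 with an estimated correlation). The hairpin 2 median of the ribosomal list lay at percentile 86.3 of matched random lists, within their usual range, and hairpin 2 ratios were higher for more strongly expressed genes (Spearman correlation of 0.23 across genes). RPLP0 was at 18.1, 27.4 and 24.8 RPKM.

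Proliferation lists were lower in hairpin 1, and closer to the control in hairpin 2. G2/M and mitosis genes had medians of -1.04 in hairpin 1 and -0.16 in hairpin 2, and 25 of 34 members were lower and 0 higher in both (camera adjusted p = 6.57e-07, and adjusted p = 0.793 with an estimated correlation). In hairpin 1 20 members were at least 2-fold lower and in hairpin 2 1 was. PRC1, a spindle midzone protein gene, was at 56.5, 19.6 and 26.7 RPKM, and CENPA, the centromeric histone gene, at 15.1, 4.76 and 8.77. E2F targets and DNA replication genes had medians of -1.02 and -0.09, with 21 of 37 lower in both (camera adjusted p = 1.39e-05, and adjusted p = 0.793 with an estimated correlation). The hairpin 2 median of this list lay at percentile 20.1 of matched random lists, within their usual range. Those of the G2/M and replication-dependent histone lists lay lower, at percentiles 0.49 and 0.95. CCNE2, which encodes cyclin E2, was at 11.04, 2.89 and 6.88 RPKM, and the thymidylate synthase gene TYMS at 143, 73.3 and 91.1. Replication-dependent histone genes had medians of -1.03 and -0.25, with 21 of 26 lower in both (camera adjusted p = 1.99e-06, and adjusted p = 0.793 with an estimated correlation). H4C9 was at 18.7, 4.69 and 6.71 RPKM, though near-identical histone copies can share reads. With hairpin 1 as the reference the 3 lists were higher in the other libraries, at camera adjusted p = 2.76e-20 for G2/M, 4.86e-20 for E2F and 1.45e-12 for histone genes (adjusted p = 0.913 for each with an estimated correlation). In the 3 lists 0 members were called over all genes or adjusted over the list alone.

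Collagen and extracellular matrix genes were lower in both hairpins, with medians of -0.39 and -0.84. Hairpin 2 also lay below hairpin 1, by a median difference of -0.42 (percentile 0.09 of matched random lists). Camera called the list with hairpin 2 as the reference too, so hairpin 2 stood apart as well as the control. Of 27 tested members 17 were lower and 2 higher in both (camera adjusted p = 2.77e-05, and adjusted p = 0.793 with an estimated correlation). COL11A1 was lower when adjusted over the list alone, and 0 members were called over all genes. COL3A1 was at 2.80, 0.239 and 0.0524 RPKM, COL5A2 at 3.52, 0.799 and 0.405, and the fibronectin gene FN1 at 107, 32.7 and 49.998. TNC, the tenascin-C gene, lay on the other side at 14.6, 44.2 and 32.1. In osteoblast lineage genes 4 of 10 were lower and 2 higher in both, with medians of -0.34 and -0.39 (camera adjusted p = 0.316). Among them the bone transcription factor gene RUNX2 was at 4.78, 0.966 and 0.7804 RPKM, the osteonectin gene SPARC at 470, 225 and 264, and the osteopontin gene SPP1 at 8.05, 45.6 and 19.997. TGF-beta and SMAD targets had 9 of 16 lower and 5 higher in both (camera adjusted p = 0.128), and BMP4 (26.3, 7.34 and 7.33) and TGFB2 (57.4, 12.8 and 3.49) were lower when adjusted over the list alone.

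Neural and embryonic kidney line markers, included as markers of other cell types, were lower with medians of -0.69 and -0.70. Of 7 tested 5 were lower and 1 higher in both (camera adjusted p = 0.0131, and adjusted p = 0.793 with an estimated correlation). SOX2 (2.61, 0.338 and 0.144 RPKM) and the neuronal tubulin gene TUBB3 (9.07, 3.26 and 2.12) were lower when adjusted over the list alone. The call was lost among genes with a mean RPKM of at least 5 (camera adjusted p = 0.465). Keratinocyte and epithelial markers had 2 of 5 higher and 2 lower in both (camera adjusted p = 0.908). KRT18 was at 2.89, 3.86 and 9.65 RPKM and EPCAM at 4.82, 2.05 and 3.44.

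The lists closest to the function of ZMYND11 were not called. RNA polymerase II elongation factors had medians of 0.15 in each hairpin, with 18 of 32 higher and 8 lower in both (camera adjusted p = 0.210). SUPT16H, a subunit of the FACT histone chaperone, was at 65.9, 30.9 and 42.0 RPKM, and SUPT5H, a subunit of the elongation factor DSIF, at 11.3, 23.2 and 14.9. H3.3 and H3K36 methylation machinery had 2 of 20 higher and 6 lower in both (camera adjusted p = 0.491), with H3-3A, which encodes H3.3, at 25.7, 15.5 and 17.4. Other PWWP and H3K36me3 reader genes had 3 of 17 higher and 9 lower in both (camera adjusted p = 0.403). PSIP1, which encodes the reader LEDGF, was at 132, 63.6 and 89.9 RPKM and the mismatch repair gene MSH6 at 60.1, 25.9 and 53.5. Core spliceosome and SR protein genes had 6 of 31 higher and 8 lower in both (camera adjusted p = 0.908), and the nuclear long noncoding and small RNA host genes 7 of 15 higher and 0 lower (camera adjusted p = 0.0594), with SNHG15 at 2.72, 5.96 and 5.42. Oncogenes and tumour suppressors went both ways, 12 of 30 higher and 11 lower in both (camera adjusted p = 0.577). The receptor gene EGFR was at 1.26, 4.55 and 8.58 RPKM. That list includes ZMYND11 itself.

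Several stress and signalling lists differed in direction between the hairpins. Interferon-stimulated genes had a median of 0.08 in hairpin 1 and -0.84 in hairpin 2 (camera adjusted p = 0.0606). Among them IFIT1 was at 2.43, 0.757 and 0.135 RPKM and IFI44 at 14.5, 5.08 and 7.84. These examples were lower in both hairpins, while 10 of 19 members were higher in hairpin 1 and 3 in hairpin 2. Heat shock protein genes had -0.31 and 0.58 (camera adjusted p = 0.577), with HSPA1B, which can share reads with its near-identical copy HSPA1A, at 35.6, 31.7 and 78.9. YAP/TEAD targets had 0.31 and -0.24 (camera adjusted p = 0.364), though ANKRD1 was higher in both hairpins, at 126, 467 and 248. Each hairpin has 1 library, so no replicate test of the difference between hairpins is possible.

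The remaining lists were not called and had medians within 0.32 of 0 in each hairpin. Adhesion and epithelial or mesenchymal genes had 7 of 18 higher and 4 lower in both (camera adjusted p = 0.364). Adjusted over the list alone, the integrin gene ITGA2 was higher (5.41, 21.5 and 30.9 RPKM) and SNAI2, which encodes the transcription factor Slug, lower (12.4, 3.18 and 3.40). Unfolded protein and ATF4 response genes had a camera adjusted p of 0.309, with MTHFD2 at 34.7, 58.5 and 57.03 RPKM. Cholesterol synthesis genes had one of 0.418, with 12 of 21 lower and 4 higher in both. HMGCS1, at 69.1, 159 and 135, was among the higher ones. Housekeeping genes had a camera adjusted p of 0.316, with RAB7A at 274, 495 and 399. Hypoxia and glycolysis genes (0.908) held the prolyl hydroxylase gene P4HA2 at 29.6, 6.03 and 8.85. Oxidative phosphorylation genes (also 0.908) had 18 of 43 lower and 9 higher in both. COX7C, a subunit of cytochrome oxidase, was at 65.4, 276 and 295, the 1 member at least 2-fold higher in both. The median over members and the direction of the camera test had opposite signs for the oncogene, keratinocyte, hypoxia and oxidative phosphorylation lists, and the mean and median did for the oncogene, hypoxia and YAP/TEAD lists.

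**Figure D3:**
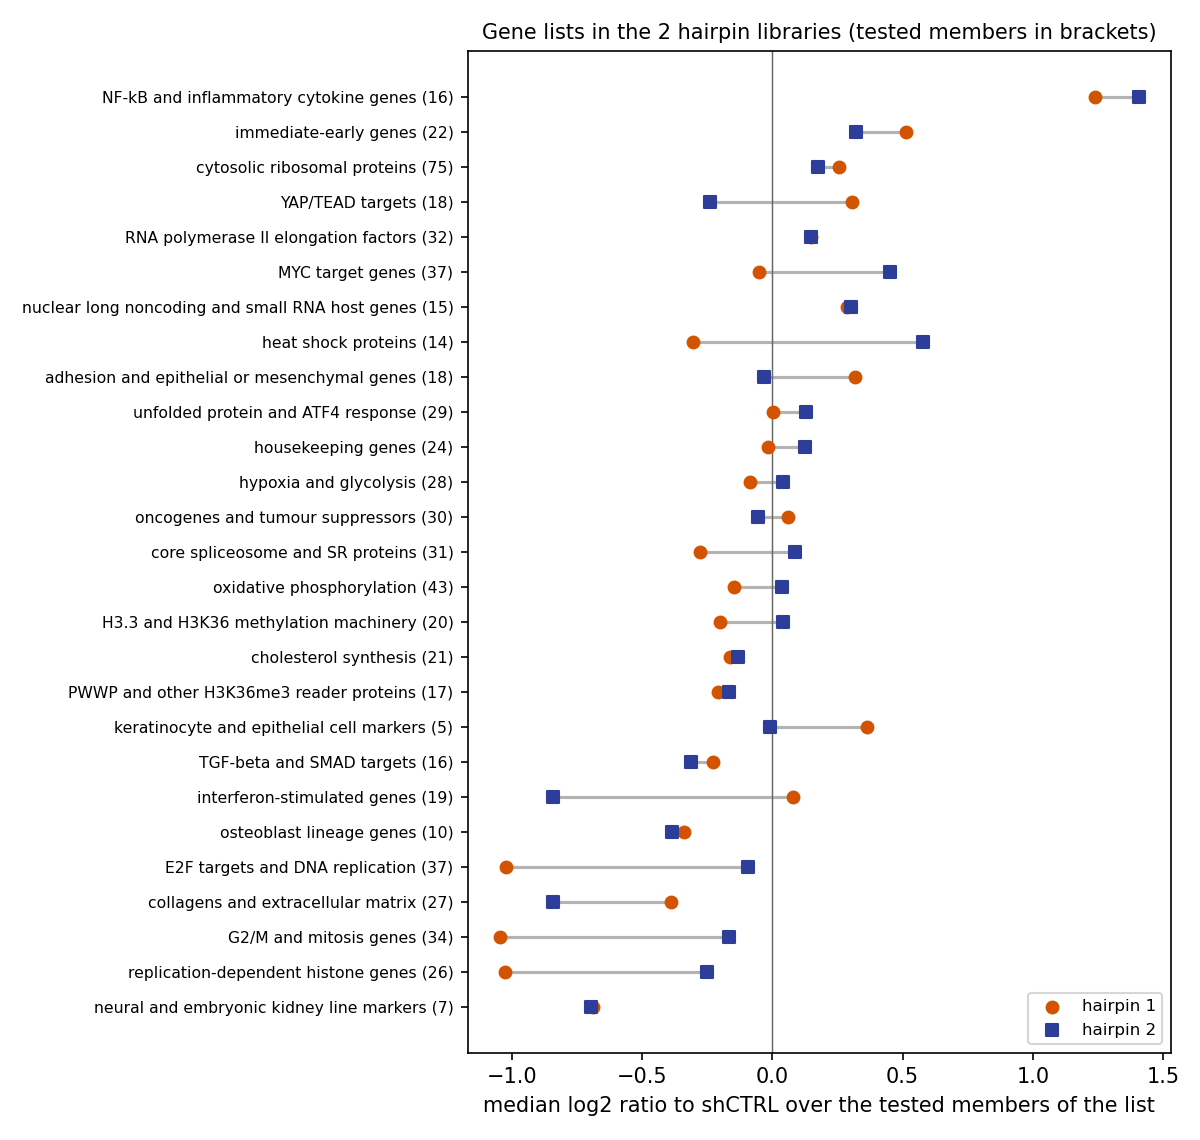
Median log2 ratio of (RPKM + 0.5) to shCTRL (x axis) over the tested members of the gene lists described here that have at least 3 tested members, with hairpin 1 as circles and hairpin 2 as squares joined by a line. The NF-kB list lies farthest right in both hairpins (1.24 and 1.41), while the G2/M list lies at -1.04 in hairpin 1 and -0.16 in hairpin 2.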

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

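The 1 result here came from transcripts that the gene comparisons leave out because no gene symbol matched them. Of 595 such transcripts with a mean RPKM of at least 1, 10 were at least 2-fold higher than shCTRL in both hairpin libraries and 15 were at least 2-fold lower. They are listed because the values lay above the control library in data outside the main measurement. The shares, 1.68% higher and 2.52% lower, are near those among named genes, 1.67% and 2.05%, so the count does not stand out. They were counted per transcript, so isoforms of a gene can count more than once.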

How the results depend on the processing

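The 4-fold and no-small-RNA counts, ZMYND11 with a hairpin left out, and gene and list tests with a hairpin library as the reference (with an estimated correlation too) were chosen after seeing the data. The count of 0 genes called by limma stood at 0 with a pseudocount of 1, without the filter, under both scalings, with the mean over transcripts, without the trend, with robust fitting and with each hairpin library as the reference. It became 1 with a pseudocount of 0.1 (MYCT1, limma adjusted p = 0.0246), 2 at a mean RPKM of at least 5 (MYCT1 at 0.0192 and MMP3 at 0.0354), where fewer genes were tested, and 1 at an adjusted p under 0.1. With hairpin 1 or hairpin 2 left out no residual degree of freedom remains, so no test can be run. The genes at least 2-fold from shCTRL then numbered 1077 without hairpin 1 and 1066 without hairpin 2, against 367 with both required.

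The count of 367 moved to 184 at a mean RPKM of at least 5, 1009 at 1.5-fold and 53 at 4-fold, as other thresholds or fewer genes would give. Under the other alternatives it lay between 272 and 472. Its split of 165 higher and 202 lower became 180 and 184 with median-ratio scaling and 193 and 179 with quantile normalization. At a mean RPKM of at least 5 it was 97 and 87, so which direction held more genes depends on the scaling and the filter. The correlation between hairpins lay between 0.460 and 0.470. The mean log2 ratio of ZMYND11 was -2.31 over all its transcripts and -2.34 with median-ratio scaling, and -2.65 to -2.13 with a hairpin left out.

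Of 10 lists called, 0 held with an estimated correlation, which has 1 residual degree of freedom behind it and does not exist for the list of 1 gene. With hairpin 1 as the reference and an estimated correlation 0 were called too. A list could hardly pass with 1 residual degree of freedom, so these counts of 0 weigh neither for nor against the lists. The number was 12 with median-ratio scaling and 11 at a mean RPKM of at least 5. With a hairpin left out and no test, 6 to 8 lists had a median of at least 0.5 in size. The MYC target list reversed to a median of -0.05 (-0.0503) without hairpin 2 and was 0.45 (0.451) without hairpin 1, so its direction came from hairpin 2. The neural list lost its call at a mean RPKM of at least 5 (camera adjusted p = 0.465). With median-ratio scaling the nuclear noncoding RNA and interferon lists passed (0.0478 each), and at a mean RPKM of at least 5 the interferon (0.0333) and TGF-beta (0.0333) lists did; the cause was not tested. Depth limits the lowest values: 3 reads on 2 kb are 0.0539 to 0.0703 RPKM, just under the control values of MYCT1 (0.0756) and SERPINB2 (0.0804). No paired analysis was possible because the control has 1 library and shares 1 replicate number with the hairpins.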

Other observations

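The 2 hairpin libraries also differed from each other, which the comparison with shCTRL averages over. At least 8-fold apart were 25 genes higher in hairpin 1 and 1 higher in hairpin 2, and at least 4-fold apart 140 and 30. The genes named here were chosen after their values were seen, and none of these differences was tested. Hairpin 1 had more RNA of GPNMB, a transmembrane glycoprotein gene, at 64.6 RPKM in shCTRL, 127 in hairpin 1 and 3.99 in hairpin 2. Likewise higher there were CPE (8.87, 17.7 and 0.489), CRYAB (109, 207 and 18.96), the receptor tyrosine kinase gene AXL (59.4, 50.7 and 4.56) and TIMP2, an inhibitor of matrix proteases (51.0, 67.1 and 6.21). The pregnancy-specific glycoprotein genes PSG4 (0.569, 19.7 and 0.760), PSG5 (0.391, 7.31 and 0.114) and PSG9 (0.540, 8.06 and 0.316) were high in hairpin 1 as well, though these near-identical genes can share reads. Hairpin 2 had more RNA of the urokinase gene PLAU (6.05, 8.29 and 66.7), ESM1 (0.811, 3.46 and 27.2), G0S2 (1.20, 3.31 and 29.6), SAA1 (1.52, 0.885 and 9.51) and HMGA2 (9.06, 13.02 and 66.1), of which ESM1 and G0S2 were at least 2-fold above shCTRL in both hairpins. In hairpin 1 the ubiquitin-conjugating enzyme variant gene UBE2V1 was at 36.9 RPKM, against 164 in shCTRL and 215 in hairpin 2, and GMNN, the geminin gene, at 1.27 against 7.01 and 9.51.

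As a description of these libraries, some lists fixed before the data were examined had unlike values in the 2 hairpins. The interferon list had a median difference, hairpin 2 minus hairpin 1, of -0.89, below all 10000 matched random lists. The heat shock list, at 0.79, lay above all 10000. Random lists treat members as independent, and with hairpin 1 as the reference 0 lists were called by camera with an estimated correlation. That version could hardly call any list with 1 residual degree of freedom. Across genes the log2 difference between the hairpins had a Spearman correlation of 0.26 with the mean level.

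Of the tests in the paragraphs that follow, those on depth for the cell-cycle lists and on weakly expressed genes were set before their results were seen; the other tests were chosen after. Through its 16 tested members of 29, the NF-kB list was higher in both hairpins. The smallest list median over 2 hairpins and 2 scalings was 1.08, which argues against library scaling. Blood cells in the cultures are also argued against, since the 15 blood markers other than CD68 stayed at or under 0.307 RPKM in the 2 hairpin libraries (in shCTRL, CD34 was at 1.13). A deviation of the single control library cannot be told apart from an effect of ZMYND11 loss, because both predict the same camera adjusted p of 1.55e-14 with shCTRL apart from the hairpins (adjusted p = 0.793 with an estimated correlation). That loss of ZMYND11 may raise these genes is an open hypothesis, which 1 control library cannot test.

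Cell-cycle lists were lower in hairpin 1 than in hairpin 2, and all 34 G2/M members had the lower value in hairpin 1. The smallest median difference for the G2/M list was 0.79 over 2 scalings (0.792), which argues against library scaling. Among the 28 members with a mean RPKM of at least 10 it was 0.891, which argues against the lower depth of the hairpin 1 library. ZMYND11 stood 7.29 percentage points of the control level lower in hairpin 1, so a dose effect of the knockdown and an effect of hairpin 1 on other genes both stay open, since 2 hairpins give no trend. Slower growth of the hairpin 1 culture may accompany either, and was not tested.

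At 2-fold fewer genes set shCTRL apart from the other libraries (367) than set hairpin 1 (427) or hairpin 2 (415) apart, while at 4-fold (53, 52 and 46) and 8-fold (9, 13 and 3) shCTRL lay above hairpin 2. Noise of weakly expressed genes stays open. Among 3839 genes with a mean RPKM of at least 10 the counts were 111 for shCTRL, 158 for hairpin 1 and 104 for hairpin 2. The hairpin counts were thus 1.42 and 0.937 times that of shCTRL. The smaller ratio met the bound set beforehand for arguing against noise, but by less than the SD of the 2 ratios (0.344). That SD is not an error of either count, which 1 library per line cannot give. The largest chromosome median was 0.196 in size, on chromosome 19 between the hairpins, which argues against larger whole-chromosome copy-number shifts between the stable lines. Smaller shifts, and changes in part of a chromosome or of the cells, were not tested and stay open. Drift between stable cultures, culture state and hairpin effects on other genes stay open as possible explanations, and 1 library per line cannot separate them.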
